A study of Homo sapiens with 8 samples.

How the data were processed

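SON TSA-seq libraries from 786-O cells treated for 3 h with DMSO or 2 µM PT2399 were compared, with 2 SON pulldowns and 2 inputs per treatment, 8 libraries in all. Groups were taken from the sample titles, since in 4 of the 8 libraries the antibody or treatment field disagreed with the title; under those fields the DMSO pulldowns would be PT2399 inputs and the PT2399 inputs would be DMSO pulldowns. The direction of each change rests on the names of the value columns, control and treatment, with DMSO as the control. Per the labels' protocols, chromatin near SON was labelled with tyramide-biotin on attached cells and the DNA was sheared before pulldown.

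The submitters' processing notes name Bowtie2, Picard, DiffBind, bedtools and the build hg19, with no versions, roles or settings. How the inputs were used, how reads were counted, how libraries were scaled and which windows were tested are not given in the sources used here. Per the file headers, the deposited tables give for each window log2 concentrations (control, treatment and their mean) and a log2 fold. The deposited fold equals control minus treatment concentration to within 0.01, and its sign was turned here so that changes are PT2399 minus DMSO. Per the file headers, the deposited tables also give a p-value and an FDR for each window, and the FDR is what the Benjamini-Hochberg method gives when applied within each 100 kb set to about 11730 windows. The group values are the authors' means over libraries, so no standard deviation or number of replicates goes with them. The authors also deposited lists of lower windows and of their genes, which hold positions or symbols and no measurement.

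The tables cover 9 sets of 100 kb windows (step 10 kb) and 9 sets of 50 kb windows (step 5 kb), with 30924 and 61882 windows a set. Windows with a mean concentration below 0 made up 61.7% and 59.9% of all windows, and the lowest values were -0.07 for DMSO and -0.11 for PT2399, which are called the floor. Windows with a log2 concentration of at least 2 in both treatments were called measured, a minimum chosen after the deposited lower list was seen to follow it for PT2399. Depth per library is unknown. The linear concentrations of a 100 kb set summed over windows at or above the minimum to a PT2399 total that was 91.9% of the DMSO total (median over sets).

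The deposited unit did not allow a count test, so the test fixed for this case was the authors' FDR at a maximum of 0.01. Windows past it were counted per direction and merged into regions over the 9 sets when they overlapped by at least 1 bp. As an alternative chosen after seeing the data, each set was recentred on the median fold of its measured windows. The standard error of a window was taken as its absolute fold divided by the normal quantile of its p-value, and windows with an absolute fold under 0.1 or a p of 0.5 or more took the median of 20 concentration bins. New two-sided normal p-values were adjusted by Benjamini-Hochberg over the measured windows of the set. This was tested on a simulated 100 kb set of 10015 windows with 200 changed and an offset of 0.12. Lower and higher changes were equal in number and lay at high concentrations only. Errors were normal and drawn from the same implied standard errors, so the simulation cannot check whether those errors hold in the data. Recentring recovered 65% of changes of 0.5 and 97.5% of changes of 1, with 1 and 0 false calls; without it there were 29 and 31 false lower calls.

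Lists of genes were fixed before the data were examined: HIF-2 targets, glycolysis, angiogenesis and extracellular matrix, lipid storage and sterol metabolism, p53 targets, nuclear speckle proteins, ribosomal proteins, renal tubule lineage and olfactory receptors. Members were counted in the deposited 100 kb and 50 kb gene lists by symbol, with older symbols updated through a RefSeq gene table of assembly GRCh38. Of the 1023 and 258 listed genes, 982 and 251 matched. That table was used for names, chromosomes and neighbourhood only, since its coordinates are of another build. Shares carry Wilson 95% intervals, which cover counting error only. The rule for named genes, with no gene positions on hg19, was HIF-2 targets in either list, 8 HIF-2 targets regardless (1 of them is not reported here), members of other fixed lists in either list (at most 5 a list) and the first 20 genes of the 50 kb list. Regions were named by lowest FDR, 10 in each direction among measured regions.

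Alternatives covered the FDR threshold, adjustment over all sets, single sets, agreement of at least 5 sets, a concentration filter, centring, a minimum fold, the overlap rule and the window size. Tests of gene list shifts along the genome and any test on values per library were left out, because they need gene positions on hg19 and values per library. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.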

Results

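SON TSA-seq was used to ask which parts of the genome lay nearer to or farther from nuclear speckles after 3 h of HIF-2α inhibition in 786-O cells, a human clear cell renal carcinoma line. SON is a core protein of nuclear speckles, the nuclear bodies rich in splicing factors, and the assay deposits biotin on DNA around the SON antibody, so that pulled-down DNA is enriched for chromatin near speckles. Cells received either DMSO vehicle or 2 µM PT2399, a small molecule that blocks HIF-2α from pairing with its partner ARNT. The series holds 8 libraries, with 2 SON pulldowns and 2 inputs for each treatment. In 4 of the 8 libraries the title and the antibody or treatment fields disagreed, and the titles were followed here.

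The values are log2 concentrations of SON signal, which the authors gave as 1 mean per treatment for each genomic window, with a fold, a p-value and an FDR. They cover 9 sets of 100 kb windows shifted by 10 kb and 9 sets of 50 kb windows shifted by 5 kb, on hg19. No value per library was analysed here, so the depth of each library is unknown and no spread between replicates could be computed. The FDR in the authors' deposited tables is the measure of error throughout, and since the labels do not say whether the 2 replicates came from separate cultures, it may reflect technical spread only. Changes are given as PT2399 minus DMSO, so that a negative change is a lower SON signal with PT2399. A window counted as measured when its log2 concentration was at least 2 in both treatments, which held for between 9995 and 10071 of the 30924 windows of a 100 kb set.

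The comparison of PT2399 with DMSO gave larger changes at particular regions, beside a small shift of the measured windows as a whole. The median change over measured 100 kb windows was -0.13 in the authors' deposited tables, and 67.6% of these windows were lower with PT2399. Over all windows, most of them at the floor, the median was -0.04. That value is the gap between the floors, -0.07 for DMSO and -0.11 for PT2399, and no measured change. Whether the shift of measured windows lies in the signal or in the scaling was not settled by these tables. On chromosome 10, a region at 73810001 to 74180000 had the lowest FDR of the measured 100 kb regions, and its best window went from 11.02 with DMSO to 10.16 with PT2399, a change of -0.86 that left 55.1% of the DMSO level (FDR 3.57e-19 in the authors' deposited table). A region at 206120001 to 206330000 on chromosome 1 changed by -1.14, from 9.75 to 8.61 (FDR 6.68e-10 in the authors' deposited table). On chromosome 5, a region at 135130001 to 135530000 changed by -1.44, from 9.53 to 8.09 (FDR 3.27e-08 in the authors' deposited table).

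**Figure D1:**
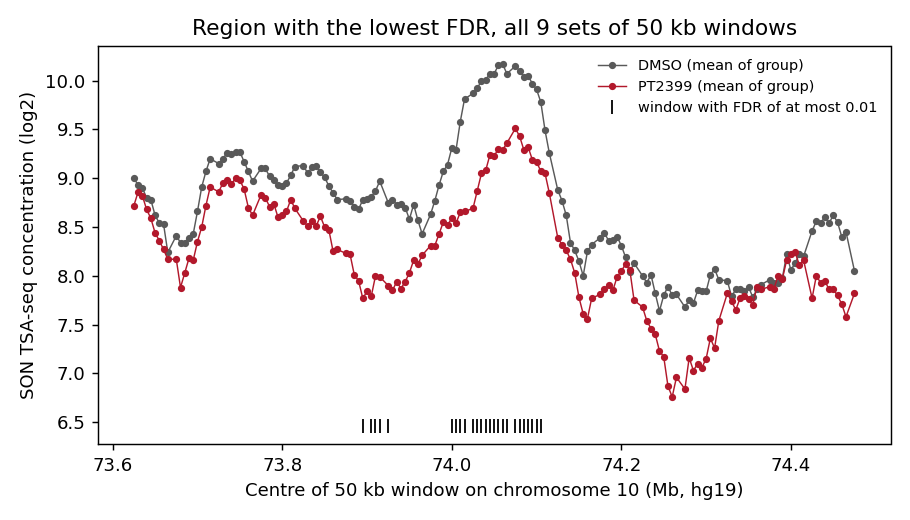
SON TSA-seq concentration (log2) with DMSO (grey) and PT2399 (red) across part of chromosome 10 (hg19), each point the authors' mean of a group for 1 window of 50 kb, placed at its centre, from all 9 window sets. Black ticks mark windows with an FDR of at most 0.01; the PT2399 line runs below the DMSO line at most points, and the 50 kb region at 73975001 to 74130000 has a change of -1.16 in its best window.

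At an FDR of at most 0.01, 1709 of the 100 kb windows were lower and 386 higher with PT2399 in the authors' deposited tables, which merged into 494 lower and 171 higher regions. Over all called windows, 81.6% were lower. Among measured windows there were 1403 lower and 77 higher, in 353 and 45 regions, so that 94.8% of these calls were lower. The minimum for a measured window left out 306 of the 1709 lower windows and 309 of the 386 higher ones. The lower measured windows had a median change of -0.44 (quartiles -0.63 and -0.34), and their regions covered 50.54 Mb. The share of lower calls among measured windows depended on the scaling between treatments. As an alternative chosen after seeing the data, the change of each set was recentred on the median of its measured windows, with a standard error implied by the deposited fold and p-value. Then 147 windows were called lower and 97 higher, in 61 and 49 regions, and 60.2% of the calls were lower. With the same implied error and no recentring, 1258 windows were called lower and 61 higher, or 95.4% lower. All 1403 windows called lower as deposited kept a recentred change below 0, since the smallest of their changes was -0.18.

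All 10 of the measured lower regions with the lowest FDR were still called after recentring. Recentred changes of their best windows ran from -1.31 to -0.22, against -1.44 to -0.34 as deposited. Chosen by lowest FDR, these 10 were the likeliest to be called again. Of all 353 lower measured regions, 61 had a called window after recentring. The region on chromosome 10 had a recentred change of -0.74 and a lowest Benjamini-Hochberg adjusted p of 1.28e-13, and the region on chromosome 5 at 135130001 to 135530000 had -1.31 and 5.14e-06. The other regions among these 10 lay on chromosome 17 at 77980001 to 78610000, where the best window changed by -0.49 (FDR 2.72e-12 in the authors' deposited table), and on chromosome 9 at 139580001 to 139960000, where it changed by -0.34 (FDR 2.7e-11). In the authors' deposited tables, the region at 35750001 to 36070000 on chromosome 22 changed by -0.71, and the region at 69360001 to 69650000 on chromosome 11 by -0.60. Regions at 3300001 to 3780000 and 23700001 to 23860000 on chromosome 1 changed by -0.55 and -0.57, and a further chromosome 5 region, at 1310001 to 1740000, by -0.57, again in the authors' deposited tables. Of the 10 regions, 9 were called in all 9 window sets, and the sets overlap, so that they are not replicates of each other.

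**Figure D2:**
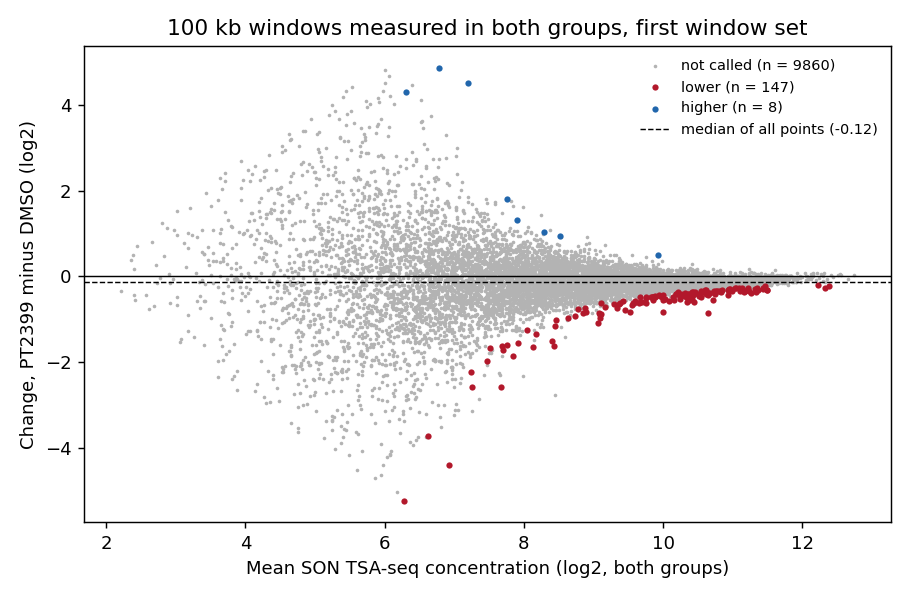
Change in SON signal (PT2399 minus DMSO, log2) against the mean concentration of both treatments (log2) for the measured 100 kb windows of the first window set, with 147 windows called lower (red), 8 called higher (blue) and 9860 not called (grey) at an FDR of at most 0.01. The dashed line is the median of all points, -0.12, and most red points sit at high concentrations where the spread is narrow. Over all 9 sets, 94.8% of the called measured windows were lower as deposited. With implied errors the share was 95.4% without recentring and 60.2% after recentring on the median.

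Regions that were higher with PT2399 were fewer than lower ones as deposited. Among measured regions, the lowest FDR belonged to a region on chromosome 17 at 66160001 to 66380000, which went from 3.11 to 8.17, a change of 5.05 (FDR 4e-06 in the authors' deposited table). On chromosome 15, a region at 38930001 to 39040000 went from 6.78 to 8.62 (FDR 2.96e-05 in the authors' deposited table). On chromosome 4, a region at 7120001 to 7250000 rose from 8.59 to 9.46, a change of 0.86 (FDR 0.000271 in the authors' deposited table). The DMSO concentration of the best window was below 4 in 7 of the 10 measured higher regions with the lowest FDR and in 18 of all 45, and large folds from so low a level carry little signal on one side. The other regions among these 10 started from low levels in most cases. In the authors' deposited tables, regions on chromosome 8 at 123970001 to 124150000, chromosome 2 at 217750001 to 217870000 and chromosome 10 at 128920001 to 129020000 each started from 2.05 and changed by 5.58, 5.58 and 5.46. Regions on chromosome 7 at 155600001 to 155710000 and 105200001 to 105300000 changed by 4.51 and 4.87, from 3.62 and 2.87, in the authors' deposited tables. A chromosome 15 region at 80260001 to 80360000 changed by 5.32 from 2.20, and a chromosome 1 region at 230300001 to 230460000 by 2.41 from 6.11, again in the authors' deposited tables. Some of these 10 regions overlapped a higher region called with DMSO below the minimum. The chromosome 17 and chromosome 2 regions overlapped ones whose best windows had DMSO at 1.21 and 0.90. The chromosome 10 region and the chromosome 15 region at 80260001 overlapped ones with DMSO at -0.07. Recentring adds to every change and so is no check on higher calls, and with the implied error 32 of the 45 regions were called under it. With windows below the minimum included, the lowest FDR was that of a chromosome 2 region at 11470001 to 11630000 (1.75e-09 in the authors' deposited table), where DMSO stood at 0.54.

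The 50 kb windows gave the same direction in fewer calls. In the authors' deposited tables, 979 windows were lower and 280 higher, in 384 and 132 regions, and among measured windows 638 were lower and 52 higher. The region with the lowest FDR was again on chromosome 10, at 73975001 to 74130000, where the best window changed by -1.16, from 9.81 to 8.66 (FDR 5.73e-14 in the authors' deposited table). A region on chromosome 5 at 6680001 to 6735000 changed by -4.58, from 8.13 to 3.56 (FDR 3.44e-08 in the authors' deposited table). The PT2399 level was below 4 in this and 3 more of the 10 measured lower 50 kb regions with the lowest FDR, and such folds too carry little signal on one side. The median change over measured windows was -0.12. After recentring, 71 windows were called lower and 30 higher, or 70.3% lower against 93.6% with the same implied error and no recentring. Of the 234 lower measured regions at 50 kb, 166 (70.9%, Wilson 95% interval 64.8% to 76.4%) overlapped a lower measured region at 100 kb, and 145 of the 353 regions at 100 kb (41.1%) overlapped one at 50 kb. Both window sizes come from the same libraries, so this overlap is no independent check, and no overlap by chance was computed.

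The authors' own list of lower windows held 1403 windows at 100 kb and 638 at 50 kb. These were exactly the windows with an FDR of at most 0.01, a lower concentration with PT2399 and a PT2399 concentration of at least 2, with the lowest listed at 2.02. Left out by that rule were 306 lower windows at 100 kb and 341 at 50 kb in which the PT2399 signal lay below that minimum. A list of higher windows was not used here.

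Lower regions were spread unevenly over the chromosomes. The shares of calls were not matched on SON level, which the calls followed, as given below. They therefore do not compare the size of the change between chromosomes. Chromosome 22 had the highest share of measured 100 kb windows called lower, 5.27%, followed by chromosome 20 with 3.20%, chromosome 1 with 3.09% and chromosome 5 with 2.76%, in the authors' deposited tables. Chromosome 3, with 0.11%, and chromosome X, with 0.03%, had the lowest shares of this kind. Chromosome X nevertheless had a median change of -0.16, so a low share of calls does not mean a small median change. At 50 kb chromosome 22 again had the highest share, 1.26%, but chromosomes 10 and 1 came next with 0.684% each, then chromosome 5 with 0.652% and chromosome 20 with 0.643%, and chromosome 13 had 0 lower windows. Chromosome 1 held 69 lower regions, chromosome 12 held 30 and chromosome 22 held 26. The median change was below 0 on 22 of 23 chromosomes and was -0.18 on chromosomes 1 and 6, -0.17 on chromosome 22, -0.07 on chromosome 3 and 0.02 on chromosome 18, where the 9 sets ran from -0.06 to 0.09. Neighbouring windows are not independent, so no test was made between chromosomes, and after recentring on the median of all measured windows the medians of 13 chromosomes lie above 0.

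**Figure D3:**
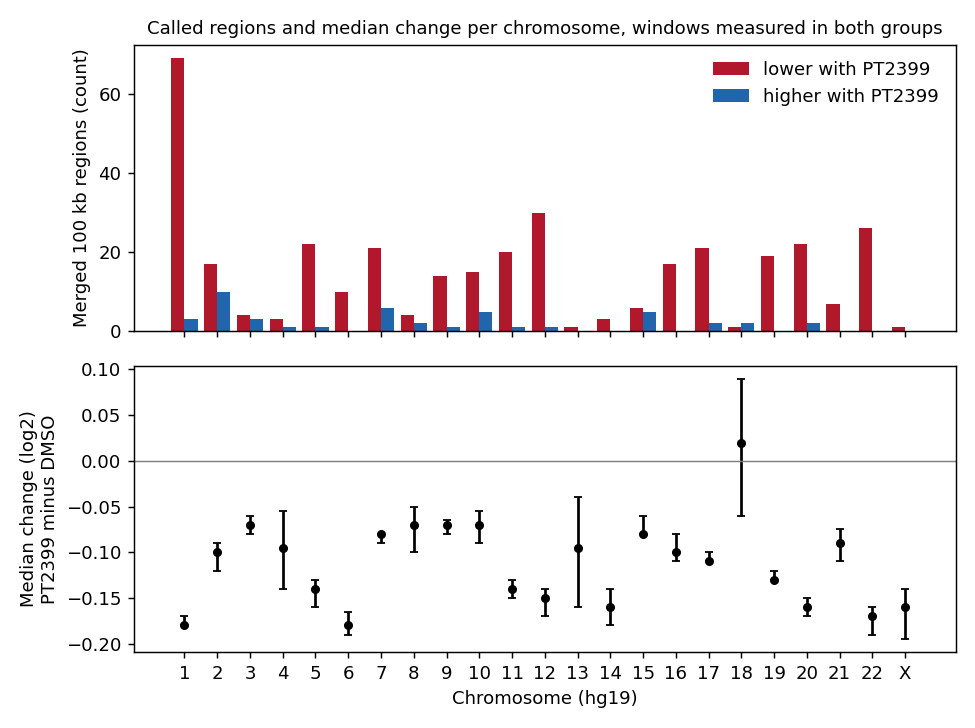
Merged 100 kb regions of measured windows called lower (red) or higher (blue) with PT2399 per chromosome (counts, top) and the median change in SON signal over measured windows (log2, bottom), with bars for the lowest and highest of the 9 window sets. Chromosome 1 holds 69 lower regions, and only chromosome 18 has a median above 0 as deposited. Recentring on the median of -0.13 raises every point by about that much. With implied errors, 317 lower and 39 higher regions were called in all without recentring, and 61 and 49 after it.

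Among measured windows, which leave out the regions of lowest SON signal, the median change varied little with mean SON concentration. Measured 100 kb windows in the top decile of mean SON concentration had a median change of -0.11, against -0.105 in the bottom decile and -0.14 in the ninth, in the authors' deposited tables. Spearman's rho across windows, which are not independent, averaged -0.008 over the 9 sets. Ranked by the DMSO level alone, which shares its error with the change, the bottom decile had a median change of 0.72, the third -0.19 and the top -0.11. The calls did follow the level, with 439 lower windows in the top decile, 383 in the ninth, 59 in the fifth and 0 in the bottom one. The width of the quartile range of the change fell from 2.12 in the bottom decile to 0.12 in the top one, so that a given change was called more readily where the signal was high.

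Some genes of the HIF-2 program were in the gene lists that the authors gave for the lower windows. The authors' deposited list of genes at the lower 100 kb windows held 1023 genes, and 4 of the 32 HIF-2 targets fixed before the data were examined were in it (12.5%, Wilson 95% interval 4.97% to 28.1%). These were CCND1, which encodes cyclin D1, SLC2A1, the glucose transporter GLUT1, SLC7A5, an amino acid transporter, and SCARB1, a receptor for high-density lipoprotein. CCND1 and SLC2A1 were also in the authors' deposited 50 kb list of 258 genes. Other well-known HIF-2 targets were in neither list, among them VEGFA, an angiogenic growth factor, NDRG1, EGLN3, LOX and ANGPTL4. Across all protein-coding genes outside the list, 4.26% were in the 100 kb list, a background that includes genes in windows too low to be called.

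Of 19 glycolysis genes, PFKP and ALDOA, both glycolytic enzymes, were in the authors' deposited 100 kb list, and SLC2A3, a glucose transporter, was in the 50 kb list. Of 19 genes of lipid storage and sterol metabolism, LPCAT1, which makes phosphatidylcholine, was in both. Of the 21 angiogenesis and extracellular matrix genes fixed beforehand, 0 were listed at either size, and of the 21 fixed p53 targets likewise 0. This leaves an upper Wilson limit of 15.5% for each. The counts hold for the members of these short lists and not for all genes of the kind. HSPG2 and TGFBI, which encode matrix proteins and are not among the 21, were listed at both sizes. Ribosomal protein genes had 2 of 79 members in the 100 kb list, RPL27 and RPLP0. Of 26 genes of nuclear speckle proteins, 0 were in the 100 kb list and PRPF4B was in the 50 kb list. Of 20 renal tubule genes, SLC12A3, a sodium chloride cotransporter, was listed at 100 kb. Olfactory receptors, which are silent in most tissues, had 4 of 390 in the 100 kb list, OR10V1, OR2AE1, OR7A17 and OR7C2, and 0 in the 50 kb list.

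The authors' deposited 50 kb list opened with ARHGEF16, MIR551A, TP73, MEGF6, WRAP73, TPRG1L, EFHD2, HSPG2, CELA3B, TCEA3, ASAP3, SFN, ZDHHC18, ADC, ZMYM1, SCMH1, SLC2A1-AS1, SLC2A1, HYI and ARTN. Of these 20, 19 were also in the 100 kb list, and over the whole of both lists 222 genes were shared. TP73 is a p53 family transcription factor, SFN encodes the 14-3-3 sigma protein and HSPG2 encodes perlecan, a basement membrane proteoglycan. Genes could not be placed in windows on hg19 here, so no gene carries a fold of its own, and how the authors assigned genes to windows is not given in the sources used here. Recentring could not be carried to the gene lists, which rest on the calls as deposited.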

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

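Settings with recentring, implied errors or measured windows alone were chosen after seeing the data; the others were fixed before. In the order lower then higher regions, 494 and 171 at 100 kb and 384 and 132 at 50 kb became 1073, 403, 1058 and 439 at an FDR of 0.05, 1545, 599, 1755 and 789 at 0.1, and 200, 73, 103 and 37 at 0.001. With Benjamini-Hochberg over all sets together they were 319, 110, 212 and 75. Single sets gave from 160 to 217 lower and 37 to 49 higher at 100 kb, and from 83 to 132 and 25 to 37 at 50 kb, since each has fewer windows. Agreement of at least 5 sets left 113, 21, 51 and 9. Measured windows alone gave 45 higher regions at 100 kb, and 234 and 30 at 50 kb. With implied errors they gave 317, 39, 174 and 17, and after recentring 61, 49, 37 and 17, where the share of lower windows fell because the shift itself was removed. For the rest the cause was not tested beyond the change of threshold. Lower regions outnumbered higher ones in every setting listed, by the least after recentring. The upper 50% of windows by concentration left the counts within 1.5 times. At 100 kb, only 11791 to 11859 windows of a set had a mean concentration above 0, close to the about 11730 of the deposited adjustment. The filter thus removed few windows that could be called and is a weak check of stability. The fold as a difference of concentrations, centring on all windows and a minimum change of 0.1 kept the deposited FDR and could not alter a count, so they show nothing about stability.

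Spearman's rho of change and SON level was -0.115 against the DMSO level in place of the mean, which shares its error with the change. The overlap of regions was 41.1% when counted from the 100 kb side. The HIF-2 targets numbered 2 in the 50 kb gene list. No paired analysis was possible because the deposited tables hold group values and not values per library. For the same reason other normalizations, leaving out each replicate and a count test were not run, and shifts of gene lists by position, with their settings of window size, gene body, nearest window, matching, loci and listed members, were not run because gene positions on hg19 were not used here. Library depth, which is unknown, limits what low windows can show.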

Other observations

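The tests of windows at or near the floor, of SON level and of HIF-2 genes against constitutive genes were chosen after the results were seen, as were the genes and families named in the next paragraph. The test of the scaling offset was fixed before its result.

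Genes outside the fixed lists were picked from the authors' deposited lists by eye, with no enrichment test, and stand for no pathway. DDIT4, an mTORC1 inhibitor induced by hypoxia, P4HA1, a collagen prolyl hydroxylase, ARNT, the partner of HIF-2α, and TGFBI, a matrix protein, were in both the 100 kb and the 50 kb list. NDUFA4L2, a mitochondrial protein that is high in clear cell renal carcinoma, HMOX1, which encodes haem oxygenase, ATF4, DDIT3 and TRIB3 of the integrated stress response, AHRR, NOTCH2 and POU5F1 were in the 100 kb list alone. Some clustered families, counted by symbol, were listed whole in the 100 kb list and others in part. Listed whole were 6 of 6 APOL genes, 4 of 4 CYP3A genes and 3 of 3 FOLR genes. Of IFITM genes, only those with a number of 1 digit were counted, and 4 of 4 were listed. In part there were 6 of 9 LCN, 4 of 6 vault RNA, 6 of 12 SPRR, 9 of 28 SNAR and 4 of 23 PRAMEF genes. So were 4 of 7 keratin genes whose symbol is KRT2 and a further digit. Neighbouring genes can share windows, though none was placed in one here. With genes under 1 Mb apart in the reference table counted as 1 locus, the 982 matched genes of the 100 kb list fell in 185 loci and the 251 of the 50 kb list in 99. On chromosome 13, the only lower measured region at 100 kb lay at 45710001 to 45830000 (change -2.98, FDR 0.000243 in the authors' deposited table), and the only listed gene matched to that chromosome was KCTD4. At 50 kb the only such region on chromosome 14, at 68225001 to 68285000 (change -2.56, FDR 0.00289 in the authors' deposited table), went with ZFYVE26. These pairings assume that no unmatched gene lies there.

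Lower calls outnumbered higher ones among measured 100 kb windows, 1403 to 77. A scaling offset between treatments may account for part of this: recentring on the median left 60.2% of calls lower, just above the bound of 60% set for an offset as the cause and well under the 80% set against it. The bounds were set for windows, which overlap between sets. Counted as merged regions, for which no bounds were set, 55.5% were lower after recentring. At 50 kb, for which no bounds were set either, 70.3% of called windows and 68.5% of merged regions were lower after recentring. Growth of the median change with SON level was tested among measured windows by a bound of 1.5 for the top decile over deciles 3 to 8. The top decile's median change was 0.846 times that of deciles 3 to 8 (-0.11 against -0.13), which argues against growth of that size. A smaller trend was not decided: the median was -0.12 in decile 2 and -0.14 in decile 9, and overlapping sets give no error for such gaps. This test was chosen after the results were seen. It does not cover the called windows, where the lower ones had a median change of -0.44. Whether the offset itself is a scaling effect or a drop in SON signal across the genome cannot be told apart, because the scaling is not stated and the deposited tables hold no reference that is known not to change. An effect of HIF-2α inhibition stays open and was not tested apart from the offset.

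Some windows were called with 1 treatment below the log2 minimum of 2, and most of these were exactly at the floor in that treatment. At 100 kb they numbered 306 lower and 309 higher (49.8% lower), of which 278 and 284 were at the floor, and at 50 kb 341 lower and 228 higher (59.9% lower). Signal crossing the floor by chance could give such calls in both directions, but the agreement between sets was mixed. Lower regions of this kind at 100 kb were called in 1.87 sets on average, against 3.10 for measured lower regions. Higher ones were called in 2.15 sets, against 1.69 for measured higher regions. Windows were split at the minimum before merging, so a locus can enter both averages. On chromosome 10, a measured higher region at 128920001 to 129020000 (1 set) overlapped one below the minimum at 128930001 to 129050000 (3 sets). The set averages therefore cannot decide, and the question stays open. No biological explanation was tested for them.

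The HIF-2 targets were in the 100 kb list more often than ribosomal and speckle protein genes, 4 of 32 against 2 of 105 (Fisher's exact test, two-sided, p = 0.0266), a difference that may reflect HIF-2 or which genes lie in windows with enough signal to be called. The 50 kb list gave a Fisher's exact p of 0.136, so the question stays open. These p-values were not adjusted, though the same comparison was made for other fixed lists. The next lowest Fisher's exact p at 100 kb was 0.111, for glycolysis. Ribosomal and speckle protein genes were listed at 1.90%, below the 4.26% of all other protein-coding genes. For the HIF-2 targets against all other protein-coding genes, Fisher's exact p was 0.0461, and 0.207 after Benjamini-Hochberg adjustment over the 9 fixed lists. Olfactory receptors alone passed that adjustment at 100 kb (Fisher's exact p = 0.000333, adjusted 0.003), being listed less often by gene, at 1.03% against 4.34%. The test counts clustered genes as independent. By locus 3 of 40 were listed, but no share by locus was computed for other genes, so this cannot be set against 4.34%. At 50 kb Fisher's exact p for olfactory receptors was 0.0243 and the adjusted one 0.217. Against ribosomal and speckle protein genes their exact p at 100 kb was 0.612. That background includes genes whose windows could not be called, so none of these values separates the treatment from the level of SON signal.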
